A study of Mus musculus with 18 samples.

How the data were processed

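RNA from 18 primary mouse mammary tumours was measured on arrays with 2 channels. Per the labels, each array carried tumour RNA labelled with Cy5 and whole-mouse total RNA labelled with Cy3 as a common reference, and the tumour channel gives the group. The groups are Wnt1 (6 arrays), Wnt1_iFGFR1 (4), Wnt1_iFGFR2 (4) and Wnt1_iR2 (4), called Wnt1, iFGFR1, iFGFR2 and iR2 here. The labels do not expand these names, and iR2 was kept apart from iFGFR2 because the submitters labelled it separately. Replicates carry numbers in accession order, which pair nothing. The sample titles carry FVB, MMTV and a number that differs on every array, but no label says that the number names an animal. No label says that the arrays come from separate animals, so every p-value measures the spread between these samples, which may be technical.

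The authors deposited 1 table of ratios on a log scale, read here as log2, for 22575 array features. The extraction of the tumour RNA by column kit and of the reference by TRIZOL is stated per the labels. The scanner, background correction, normalization and any filling of missing values are not given in the sources used here. The table held no empty cell, its values ran from -9.03 to 7.57, and the column medians lay between -0.02 and 0.01. The log base and the direction are not stated in the table. The direction was taken from the dyes, tumour over reference. Over all 18 arrays the mean ratio was 3.54 for Ehf, 3.51 for Elf5, 3.37 for Kit and 3.22 for Krt18, all genes of luminal mammary epithelium. It was -6.20 for the intestinal gene Fabp2, -5.25 for Fgb and -5.09 for Serpina1d, both made in liver, and -4.88 for the lung surfactant gene Sftpc. The base of the logarithm was taken as 2, and a fold change below rests on that reading.

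Features were named by the symbols of the platform annotation. Of its 18688 entries, 18445 had an Entrez identifier in a table of genes of assembly GRCm38.p6, used for names only, and 0 of these carried another symbol there. Members of the gene lists given by an older symbol were found through that table. A single symbol was found for 18658 features, several for 30 and none for 3887 (17.2%). Features with several symbols named no gene. Features of 1 symbol were averaged, which gave 16887 genes, all of them tested. For 1081 genes with 2 probes the median correlation of the probes over the arrays was 0.0714, and their mean ratios correlated at 0.457 across genes, so probes of a gene often disagreed. Coordinates are not given because the table names no genome build.

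Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 ratios, all 18 arrays in 1 fit without covariates), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Every adjusted p for a gene is from this fit. The comparisons were each receptor group against Wnt1, the mean of the 3 receptor groups against Wnt1, the receptor groups against each other, and an F test over the 4 groups. An effect is a difference of mean log2 ratios, given with its standard error (SE), and group levels are given as mean ± SD. The number of arrays limits the precision. In simulated data with 200 changed genes among 16887, the comparison of iFGFR1 with Wnt1 recovered 38% of genes changed by 1 log2 unit and 96% of those changed by 2, with 9 calls among unchanged genes. For iFGFR2 against Wnt1 the recovered shares were 60% and 100%, for iR2 against Wnt1 38% and 98%, and for iR2 against iFGFR2 36% and 100%. Each comparison drew its own genes, 50 of each size, so these shares do not rank the comparisons by sensitivity.

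Before the data were examined, 29 gene lists were fixed for signalling, mammary lineages, other cell types a tumour sample can hold, proliferation, translation, stress and handling. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 29 lists within a comparison, with an estimated correlation and with fry as alternatives. A list is called where its adjusted p was under 0.05. Of the 66 list calls, 6 held with an estimated correlation and 51 with fry, which asks whether a list's genes move one way and does not compare them with other genes. The named genes were fixed by rule as well. They are the transgene-related genes (Wnt1, Fgfr1, Fgfr2, Fkbp1a), the 8 largest rises and 8 largest falls among genes past the threshold (5 and 5 between receptor groups), and up to 4 list members past the threshold per list and comparison, by smallest p. Unnamed clones were counted and passed over when genes were named.

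Alternatives covered centring, quantile normalization, scaling to 1 median absolute deviation, array weights, robust and trended priors, the choice of probe, a variance filter, the threshold, the arrays in the fit, the number in the sample title as a covariate, and each array left out in turn. Alternatives that filter on missing values were void because no cell is empty. The title numbers ran from 5101 to 5106 on the iR2 arrays and from 2406 to 4013 on the others. That covariate is therefore nearly confounded with the iR2 group, and calls of iR2 that it ends cannot be told from an effect of the group. After the data were seen, a term for an array batch, fits without doubted arrays and a filter on the mean ratio were added. Overlaps between comparisons that share the Wnt1 arrays were set against 50 simulated draws of unchanged groups and against 20 splits of the Wnt1 arrays 3 and 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.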

Results

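The series measured gene expression in primary mammary tumours of mice whose tumours were labelled Wnt1 (n = 6) or Wnt1 together with iFGFR1, iFGFR2 or iR2 (n = 4 each). Wnt1 is a secreted ligand of the Wnt pathway, and in MMTV-Wnt1 mice a viral promoter drives it in mammary epithelium. The title places the question in the cooperation of FGF receptor and Wnt-1 signalling in mammary tumours. All values are log2 ratios of tumour RNA to a whole-mouse RNA pool. Over the 4 groups, 3311 of 16887 genes differed by limma's F test at an adjusted p under 0.05, and 6053 had an unadjusted p under 0.05. The first 3 principal components held 23.1%, 14.9% and 8.81% of the variance. No 2 arrays held identical values, and the highest correlation between arrays was 0.962.

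The genes named in the group labels were read first. Fgfr1, a receptor tyrosine kinase for fibroblast growth factors, stood at 1.59 ± 0.37 in iFGFR1 (n = 4) and 0.22 ± 0.14 in Wnt1 (n = 6), a rise of 1.38 (SE 0.18, 2.60-fold, adjusted p = 6.7e-05). All 4 iFGFR1 arrays lay above every Wnt1 array. In iFGFR2 Fgfr1 stood at 0.21 ± 0.32 and in iR2 at 0.56 ± 0.06, differences from Wnt1 of -0.01 (adjusted p = 0.984) and 0.34 (adjusted p = 0.275). Fgfr2 stood at 0.11 ± 0.31 in Wnt1, -0.58 ± 0.31 in iFGFR1, -0.42 ± 0.55 in iFGFR2 and -0.21 ± 0.35 in iR2. The differences of -0.69, -0.53 and -0.32 did not pass (adjusted p = 0.0579, 0.212 and 0.466). Where the Fgfr1 and Fgfr2 probes lie relative to any construct is not given in the sources used here. The values of either gene, the higher Fgfr1 in iFGFR1 included, therefore cannot be assigned to a transgene or to the endogenous gene, and neither checks a label. The Wnt1 gene differed from the Wnt1 group by -0.15, -0.03 and -0.06 in iFGFR1, iFGFR2 and iR2, and Fkbp1a, whose protein supplies the dimerizing domain of many inducible receptors, by -0.11, -0.14 and 0.09. None of these passed (lowest adjusted p = 0.739).

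**Figure D1:**
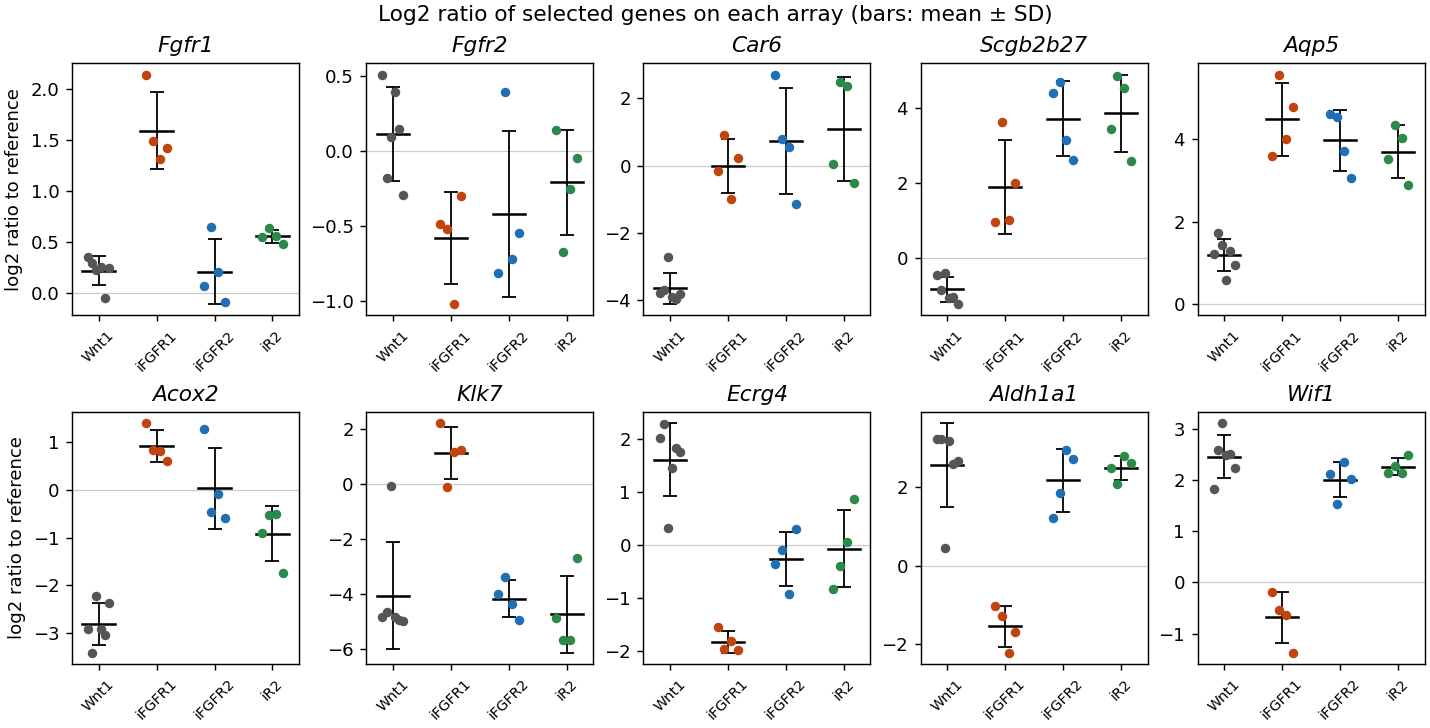
Log2 ratio to the whole-mouse reference on each array for 10 genes, by group (points: arrays; lines and bars: mean ± SD; n = 6 Wnt1 and 4 of each other group). Fgfr1 lies above every Wnt1 array on 4 of 4 iFGFR1 arrays, and Car6 and Aqp5 do so on all 12 receptor arrays.

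Across the 3 receptor groups together, Car6, Scgb2b27, Cldn10 and Aqp5 rose most against Wnt1. Car6, a secreted carbonic anhydrase, rose by 4.25 (SE 0.48, 19.1-fold, adjusted p = 3.05e-05). The secretoglobin gene Scgb2b27 rose by 4.00 (SE 0.39), the tight junction gene Cldn10 by 3.04 (SE 0.46) and the water channel gene Aqp5 by 2.85 (SE 0.29). Acox2, a peroxisomal oxidase, rose by 2.83 (SE 0.26), Spdef, a transcription factor of secretory epithelium, by 2.44 (SE 0.27) and Tpd52l1 by 2.43 (SE 0.25). Each of these 7 genes lay above every Wnt1 array on 12 of 12 receptor arrays. Ncald rose by 2.36 (SE 0.41) and was above all Wnt1 arrays on 7 of 12. Ecrg4 fell by 2.33 (SE 0.26, adjusted p = 3.05e-05, below all Wnt1 arrays on 11 of 12), the haptoglobin gene Hp fell by 2.26 (SE 0.33, 12 of 12). Crym fell by 2.17 (SE 0.51, 9 of 12) and Fibin fell by 2.10 (SE 0.39, 6 of 12). Apod, Xlr4b, Sostdc1 and Cntn1 fell by 2.02, 1.90, 1.90 and 1.88. Apod and Sostdc1 fell by more than this in iFGFR1, and neither is among the largest falls given below for iFGFR2 and iR2. Apod was also higher in iFGFR2 and in iR2 than in iFGFR1, so its pooled fall is mostly that of iFGFR1. In all, 2115 genes passed, 1166 higher and 949 lower, and 4626 had an unadjusted p under 0.05. The count was 1221 or 1224 without Wnt1 replicate 2 or 6 and 3457 with array weights. It was 659 with the number in the sample title as a covariate (433 higher, 226 lower, 492 shared with the 2115), where the calls of Hp, Crym, Apod, Xlr4b and Sostdc1 ended (adjusted p = 0.0533 to 0.424).

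Among the lists, fibroblast and matrix genes had a median of -0.44 over 27 measured genes in the 3 receptor groups (camera adjusted p = 7.6e-05, adjusted p = 0.393 with an estimated correlation). Of them 11 fell and 0 rose (13 and 0 adjusted over the list alone), and the list mean lay below that of Wnt1 on 12 of 12 arrays. Fbln1, a basement membrane glycoprotein, fell by 1.28 (SE 0.16) and S100a4, a marker of fibroblasts, fell by 1.76 (SE 0.29). Pdgfrb fell by 0.94 (SE 0.21) and Pdgfra fell by 0.93 (SE 0.22). Translation factors had a median of 0.43 over 28 (10 rose and 1 fell, 16 and 2 adjusted over the list alone, 12 of 12 arrays; camera adjusted p = 0.000122, adjusted p = 0.215 with an estimated correlation), with Eif4ebp1 up by 1.401 (SE 0.25). The list of FGF and ERK feedback genes had a median of 0.30 over 23 (6 rose and 1 fell, both ways also adjusted over the list alone, 12 of 12 arrays; camera adjusted p = 0.00253, adjusted p = 0.215 with an estimated correlation). Its risers included Ier3 at 1.10 (SE 0.18) and the ETS factor gene Etv1 at 1.24 (SE 0.26). Interferon response genes had a median of 0.47 over 22 (8 rose and 0 fell over all genes and adjusted over the list alone, 10 of 12 arrays; camera adjusted p = 0.000244, adjusted p = 0.514 with an estimated correlation). Proliferation genes had a median of 0.27 over 43 (9 rose and 0 fell by both counts, 11 of 12 arrays; camera adjusted p = 0.000493, adjusted p = 0.393 with an estimated correlation). The proliferation median was 0.54 in iFGFR1, but 0.16 in iFGFR2 and 0.098 in iR2 (camera adjusted p = 0.281 and 0.0878). For FGF and ERK feedback it was 0.46, 0.13 and 0.19 (camera adjusted p = 0.109 in iFGFR2 and 0.066 in iR2). For interferon genes it was 1.04, 0.28 and 0.36 (camera adjusted p = 0.321 in iFGFR2 and 0.0471 in iR2). Ribosomal protein genes had a median of 0.18 over 64 (15 rose and 3 fell, 23 and 4 adjusted over the list alone, 8 of 12 arrays; camera adjusted p = 0.00368, adjusted p = 0.462 with an estimated correlation). By group their median was 0.47 in iR2, but -0.02 in iFGFR1 and 0.06 in iFGFR2 (camera adjusted p = 0.756 and 0.786). Luminal epithelial genes had a median of 0.36 over 23 (7 rose and 0 fell, 10 and 2 adjusted over the list alone, 11 of 12 arrays; camera adjusted p = 0.0308, adjusted p = 0.393 with an estimated correlation), with Kit at 0.71 (SE 0.14). The luminal call was lost under quantile normalization (adjusted p = 0.0697), under scaling of each array to 1 median absolute deviation (0.127) and without any 1 of 5 arrays (highest 0.0773, with a median of 0.15 without Wnt1 replicate 6). Without that array the FGF and ERK feedback median was 0.19. Given the title number as a covariate, 5 of the 7 list calls were kept, and those of FGF and ERK feedback and of luminal genes ended (medians 0.17 and 0.11, adjusted p = 0.0865 and 0.324). Fry did not call the interferon list (adjusted p = 0.0927). List means lay past every Wnt1 array on 12 of 12 arrays for FGF and ERK feedback, 10 for translation and fibroblast genes, 5 for luminal and interferon genes and 4 for proliferation and ribosomal genes.

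In iFGFR1 tumours, Klk7, Acox2, Car6 and Pglyrp1 rose most against Wnt1. Klk7, a protease of cornifying epithelium, rose by 5.19 (SE 0.79, 36.4-fold, adjusted p = 0.000255), from -4.06 ± 1.95 (n = 6) to 1.13 ± 0.95 (n = 4), and was above every Wnt1 array on 3 of 4 arrays. Acox2 rose by 3.73 (SE 0.33), and Car6 by 3.65 (SE 0.62). The peptidoglycan receptor gene Pglyrp1 rose by 3.50 (SE 0.27), Aqp5 by 3.28 (SE 0.37) and Arg1, the arginase of alternatively activated macrophages, by 3.26 (SE 0.36). Each of these 5 lay above every Wnt1 array on 4 of 4 arrays. Apod fell by 4.63 (SE 0.66), Aldh1a1, a retinal dehydrogenase, fell by 4.09 (SE 0.44). The Wnt and BMP antagonist gene Sostdc1 fell by 3.51 (SE 0.46), Ecrg4 fell by 3.43 (SE 0.34) and Mgp fell by 3.42 (SE 0.47), each on 4 of 4 arrays. Phactr1 and Tpd52l1 rose by 3.06 and 2.99, and Fibin, Fbp1 and Sobp fell by 3.41, 3.36 and 3.15. All of these but Fbp1 (0 of 4) lay past every Wnt1 array on 4 of 4 arrays. Of 16887 genes, 2608 passed, 1415 higher and 1193 lower, with 5039 at an unadjusted p under 0.05.

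Interferon response genes had the largest list median in iFGFR1, 1.04 over 22, with 11 risen and 0 fallen (13 and 0 adjusted over the list alone; camera adjusted p = 2.12e-07, adjusted p = 0.255 with an estimated correlation). Irf7, the regulator of type I interferon induction, rose by 1.45 (SE 0.25), Bst2 by 1.92 (SE 0.35), Rtp4 by 2.78 (SE 0.57) and Usp18 by 2.26 (SE 0.48). Hypoxia and glycolysis genes had a median of 0.87 over 21, 13 risen and 0 fallen (16 and 1 adjusted over the list alone; camera adjusted p = 2.04e-06, adjusted p = 0.255 with an estimated correlation), among them Car9 at 1.46 (SE 0.23), Bnip3 at 1.78 (SE 0.32) and the prolyl hydroxylase gene Egln3 at 2.10 (SE 0.43). Proliferation genes had a median of 0.54 over 43, with 13 risen and 0 fallen (19 and 0 adjusted over the list alone; camera adjusted p = 2.98e-07, adjusted p = 0.139 with an estimated correlation), led by the mitotic genes Cdk1 at 0.90 (SE 0.16), Kif11 at 0.97 (SE 0.19) and Bub1b at 0.99 (SE 0.20). The FGF and ERK feedback list had a median of 0.46 over 23, with 8 risen and 1 fallen (9 and 1 adjusted over the list alone; camera adjusted p = 0.00105, adjusted p = 0.111 with an estimated correlation). Etv1 rose by 2.04 (SE 0.33), Hbegf, a ligand of the EGF receptor, by 1.66 (SE 0.27) and Ier3 by 1.76 (SE 0.23). Neutrophil genes had a median of 0.46 over 16, with 5 risen and 2 fallen (8 and 2 adjusted over the list alone; camera adjusted p = 0.00499, adjusted p = 0.111 with an estimated correlation), led by the calprotectin genes S100a8 at 2.56 (SE 0.38) and S100a9 at 1.59 (SE 0.27), with the attractant Cxcl1 at 1.68 (SE 0.34). Squamous keratinocyte genes had a median of 0.37 over 22, 6 risen and 0 fallen by both counts, that over all genes and that adjusted over the list alone (camera adjusted p = 0.00517, adjusted p = 0.255 with an estimated correlation). Besides Klk7, Calm4 rose by 2.18 (SE 0.49) and Krtdap by 1.86 (SE 0.44). Translation factors had a median of 0.37 over 28, with 5 risen and 0 fallen (6 and 0 adjusted over the list alone; camera adjusted p = 0.00499, adjusted p = 0.225 with an estimated correlation). Unfolded protein stress genes had a median of 0.20 over 18, with 6 risen and 0 fallen by both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.255 with an estimated correlation). In these 2 lists Eif4ebp1, Chac1, Atf4 and Asns rose by 2.27, 2.05, 1.35 and 1.23. Early response and heat shock genes, which also move with tissue handling, had a list mean of 0.51 ± 0.18 in iFGFR1 and 0.26 ± 0.10 in Wnt1. Their median change was 0.22 over 21, with 4 risen and 1 fallen (4 and 2 adjusted over the list alone), and the list was called by fry (adjusted p = 0.0271) and not by camera (adjusted p = 0.12). Ier3, Nr4a1, Btg2 and Klf6 rose by 1.76, 1.41, 1.05 and 1.02 and Egr1 fell by 1.17. Ier3 and Egr1 are also in the FGF and ERK feedback list.

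Fibroblast and matrix genes had a median of -0.60 over 27 in iFGFR1, with 11 fallen and 2 risen (12 and 2 adjusted over the list alone; camera adjusted p = 4.32e-05, adjusted p = 0.225 with an estimated correlation). Pdgfra, a receptor of mesenchymal cells, fell by 2.61 (SE 0.28), Fbln1 fell by 1.83 (SE 0.21) and Fbln2 fell by 1.23 (SE 0.19). Basal and myoepithelial genes had a median of -0.28 over 23, with 6 fallen and 1 risen (7 and 2 adjusted over the list alone; camera adjusted p = 0.00499, adjusted p = 0.111 with an estimated correlation). The contractile gene Tagln fell by 1.17 (SE 0.16), Snai2 fell by 1.70 (SE 0.30) and the basal keratin gene Krt14 fell by 1.69 (SE 0.33). The list of Wnt and β-catenin targets had a median of -0.33 over 25, with 6 fallen and 2 risen (8 and 2 adjusted over the list alone; camera adjusted p = 0.0132, adjusted p = 0.111 with an estimated correlation). The secreted Wnt inhibitor gene Wif1 fell by 3.14 (SE 0.24), the R-spondin receptor gene Lgr5 fell by 2.90 (SE 0.43) and Sfrp2 fell by 2.24 (SE 0.37), while Prom1 rose by 2.85 (SE 0.25). MHC class II genes had a median of -0.54 over 9, with 1 fallen and 0 risen (2 and 0 adjusted over the list alone; camera adjusted p = 0.0168, adjusted p = 0.139 with an estimated correlation). Cd74, the invariant chain gene, fell by 2.22 (SE 0.31). On all 4 iFGFR1 arrays the mean of each of these 12 lists lay past the Wnt1 mean in the direction of the call, and lay past every Wnt1 array on 4 of 4 for 8 of them and 3 of 4 for the translation, fibroblast, interferon and hypoxia lists. The basal median was -0.16 or -0.43 without Wnt1 replicate 1 or 2. The unfolded protein median was 0.30 and 0.33 without Wnt1 replicates 2 and 3, and 0.38, 0.33 and 0.10 without iFGFR1 replicates 1, 2 and 4. The MHC class II call was lost without Wnt1 replicate 3 (median -0.32, adjusted p = 0.051), the same fit here as the batch term given below. It was also lost with the title number (median -0.30, adjusted p = 0.166). Under scaling the unfolded protein call (adjusted p = 0.0574) and that of Fbp1 (0.0563) were lost.

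In iFGFR2 tumours Scgb2b27, Car6, Cldn10 and Hey1 rose most against Wnt1. Scgb2b27 rose by 4.57 (SE 0.51, 23.7-fold, adjusted p = 0.000292), Car6 by 4.38 (SE 0.62), and Cldn10 by 3.77 (SE 0.59). The Notch target gene Hey1 rose by 3.22 (SE 0.47), Acox2 by 2.85 (SE 0.33), Spdef by 2.83 (SE 0.35), Aqp5 by 2.77 (SE 0.37) and Padi2 by 2.67 (SE 0.42). All 8 lay above every Wnt1 array on 4 of 4 arrays. Hp fell by 2.60 (SE 0.43), S100a4 fell by 2.09 (SE 0.37), Dnajb8 fell by 2.02 (SE 0.43) and Ecrg4 fell by 1.88 (SE 0.34), each on 4 of 4 arrays. S100a6, Fibin, Trim3 and Crim1 fell by 1.98, 1.95, 1.91 and 1.77. These 4 calls ended without any 1 of 5, 8, 6 and 14 of the 18 arrays (highest adjusted p = 0.158, 0.176, 0.136 and 0.2, each without iFGFR2 replicate 1), and that of Dnajb8 ended without this array alone (0.0838). Dnajb8 also missed the threshold with array weights (0.0508), Fibin and Crim1 under scaling (0.0837 and 0.0659), Crim1 under quantile normalization (0.0554), and S100a6, Fibin and Crim1 with only the compared arrays (0.0698 to 0.11). Fgf3, an FGF ligand gene, rose by 1.51 (SE 0.39, adjusted p = 0.0375, above all Wnt1 arrays on 4 of 4), the stem cell factor receptor gene Kit by 0.99 (SE 0.18) and Prom1 by 1.88 (SE 0.25).

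Only 2 lists were called in iFGFR2. Fibroblast and matrix genes had a median of -0.50 over 27, with 2 fallen (S100a4 and Pdgfrb, the latter by -1.19, SE 0.28) and 0 risen (3 and 1 adjusted over the list alone; camera adjusted p = 0.000966, adjusted p = 0.714 with an estimated correlation). Translation factors had a median of 0.34 over 28, with 1 risen (Eif5a at 0.72, SE 0.19) and 0 fallen (7 and 1 adjusted over the list alone; camera adjusted p = 0.0176, adjusted p = 0.714 with an estimated correlation). Both list means lay past the Wnt1 mean on 4 of 4 arrays, and fry called neither (adjusted p = 0.18 and 0.0519). The fibroblast mean lay past every Wnt1 array on 4 of 4 and the translation mean on 3 of 4. The fibroblast call was lost without Wnt1 replicate 3 (median -0.28, adjusted p = 0.0506), which for this comparison is the same fit as the batch term. The translation call was lost without iFGFR2 replicate 3 (0.167) or 4 (0.0851) or with the title number (0.0575). Of 16887 genes 579 passed, 333 higher and 246 lower (316 and 140 after scaling each array to 1 median absolute deviation), with 3524 at an unadjusted p under 0.05. This count moved with single arrays, to 99, 1470, 280 and 240 without iFGFR2 replicates 1 to 4, to 209, 1414, 284, 287 and 270 without Wnt1 replicates 2 to 6, and to 371 without iR2 replicate 1. It was 143 with only the compared arrays and 1099 with iR2 pooled in. The batch term gave the same 1414 as leaving out Wnt1 replicate 3, because it is the same fit here.

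In iR2 tumours 26 of 64 ribosomal protein genes rose and 1 fell against Wnt1. Their median was 0.47 (33 and 4 adjusted over the list alone; camera adjusted p = 5.96e-15, adjusted p = 0.0555 with an estimated correlation), and the list mean was above every Wnt1 array on 4 of 4 arrays. Rplp0, Rpl19 and Rps14 rose by 1.59 (SE 0.22), 1.496 (SE 0.25) and 1.39 (SE 0.22). Translation factors had a median of 0.49 over 28, with 6 risen and 2 fallen (14 and 2 adjusted over the list alone; camera adjusted p = 3.55e-05, adjusted p = 0.0945 with an estimated correlation), led by the poly(A)-binding protein gene Pabpc1 at 2.15 (SE 0.29) and the elongation factor gene Eef1a1 at 1.17 (SE 0.23). Among single genes Car6 rose by 4.74 (SE 0.62, 26.7-fold, adjusted p = 0.000686), Scgb2b27 by 4.70 (SE 0.51), and Cldn10 by 3.02 (SE 0.59). Hey1 rose by 2.52 (SE 0.47), Aqp5 by 2.50 (SE 0.37), Spdef by 2.35 (SE 0.35) and Padi2 by 2.12 (SE 0.42). The largest falls were those of Xlr4b, Hoxa10, Crym, the histone gene H4c4, Vstm2a, Trim55, Reg1 and Vit, which fell by 2.32, 2.21, 2.21, 2.15, 2.07, 2.07, 1.96 and 1.94. The calls of Hoxa10, Crym and Xlr4b ended without any 1 of 14, 12 and 5 of the 18 arrays (highest adjusted p = 0.132, 0.153 and 0.109, each without iR2 replicate 3), and that of Vstm2a without this array alone (0.0508). Hoxa10 turned to 0.27 with the batch term given below, and the calls of Hoxa10 and Crym ended under quantile normalization (0.126 and 0.068).

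Oxidative phosphorylation genes had a median of -0.27 over 80 in iR2 (16 fallen and 2 risen, 23 and 3 adjusted over the list alone; camera adjusted p = 0.000873, adjusted p = 0.224 with an estimated correlation). Atp5k and Ndufa11 fell by 1.72 (SE 0.24) and 1.63 (SE 0.28), while the ATP synthase gene Atp5b rose by 1.41 (SE 0.29). Luminal epithelial genes had a median of 0.36 over 23 (4 risen and 0 fallen by both counts, over all genes and adjusted over the list alone; camera adjusted p = 0.0021, adjusted p = 0.172 with an estimated correlation), with Krt18 at 1.17 (SE 0.31) and Xbp1 at 1.25 (SE 0.36). T and NK cell genes had a median of -0.45 over 18 (5 fallen and 0 risen by both counts, over all genes and adjusted over the list alone; camera adjusted p = 0.008, adjusted p = 0.0555 with an estimated correlation). The lymphocyte genes Cd5, Gzma and Cd3d fell by 0.71 (SE 0.17), 1.18 (SE 0.30) and 0.80 (SE 0.22). The means of these 3 lists lay past every Wnt1 array on 4 of 4 arrays. Fibroblast and matrix genes had a median of -0.29 (2 of 27 fell by both counts, over all genes and adjusted over the list alone; camera adjusted p = 0.0183, adjusted p = 0.512 with an estimated correlation). Genes of organs abundant in the reference had a median of -0.26 over 28 (2 fell, 4 adjusted over the list alone; camera adjusted p = 0.0183, adjusted p = 0.288 with an estimated correlation), which turned to 0.07 under quantile normalization. Erythroid genes had a median of -0.59 over 6 (0 fell, 1 adjusted over the list alone; camera adjusted p = 0.0396, adjusted p = 0.18 with an estimated correlation). Early response genes had a median of 0.23 over 21 (1 rose, 3 adjusted over the list alone; camera adjusted p = 0.0441, adjusted p = 0.3 with an estimated correlation), which turned to -0.19 with the number in the sample title as a covariate and was 0.093 without iR2 replicate 1. Neutrophil genes had a median of -0.35 over 16 (1 fell, Camp, by -1.15; 4 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.0471, adjusted p = 0.224 with an estimated correlation). Interferon response genes had a median of 0.36 over 22, which turned to -0.11 with the batch term given below (0 passed by either count, over all genes or adjusted over the list alone; camera adjusted p = 0.0471, adjusted p = 0.801 with an estimated correlation). The neutrophil and interferon list means lay past the Wnt1 mean on 3 of 4 arrays and the other 9 on 4 of 4. Past every Wnt1 array lay 3 of 4 for fibroblast and neutrophil genes, 1 of 4 for interferon and early response genes and 4 of 4 for the rest. The calls of the 6 lists from fibroblast to interferon genes were lost under quantile normalization (lowest adjusted p = 0.109) and without Wnt1 replicate 3 (0.0541 to 0.242), except that the interferon call was instead lost without any 1 of 7 other arrays (highest 0.273, with a median of 0.23 without iR2 replicate 2). The neutrophil call was lost without any 1 of 8 arrays (highest 0.109), and the erythroid and early response calls without any 1 of 4 each (0.0858 and 0.236). Without Wnt1 replicate 3 the luminal median was 0.55 and the fibroblast median -0.15. The interferon call was also lost under scaling (adjusted p = 0.116), and fry called neither it (0.561) nor the fibroblast and early response lists (0.0994 for both).

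The iR2 arrays stood apart technically. The SD between features of the same gene was taken as a median over the 47 genes with 10 or more features. It was 0.0857 to 0.158 on the 4 iR2 arrays and 0.115 on Wnt1 replicate 3, against 0.241 to 0.507 on the other 13 arrays. The iR2 arrays correlated with each other at 0.933 to 0.962. Against Wnt1, 1199 genes passed, 660 higher and 539 lower (811 and 428 after quantile normalization, 1190 and 1627 after scaling), with 3944 at an unadjusted p under 0.05. With these 5 arrays as a batch term, which rests on Wnt1 replicate 3 alone, 304 genes passed, 96 higher and 208 lower, 51 of them shared with the 1199. For this comparison the term leaves Wnt1 replicate 3 as the only Wnt1 array, so calls kept or ended in that fit test no difference between the groups. The ribosomal and translation medians there were 0.28 and 0.11. The luminal, erythroid and interferon medians were -0.04, -0.49 and -0.11. The count was 725, 1883, 781 and 689 without Wnt1 replicates 2, 3, 5 and 6, and 335, 389 and 303 without iR2 replicates 1, 2 and 3. Of the 16 genes named for the largest changes, 1 kept its call with the batch term (Scgb2b27). Taking the title number as a covariate in place of that term left 52 genes, 42 higher and 10 lower, 37 of them shared with the 1199, and again Scgb2b27 alone of the 16. There 2 of the 11 list calls were kept, ribosomal (median 0.79) and oxidative phosphorylation. The translation, luminal, T and NK cell, fibroblast and reference organ calls ended (medians 0.45, 0.23, -0.0069, -0.13 and -0.093, adjusted p = 0.0564, 0.364, 0.469, 0.469 and 0.364). The erythroid, neutrophil, interferon and early response calls ended too (adjusted p = 0.299, 0.58, 0.0865 and 0.721). The count was 5207 with array weights and 2317 with only the compared arrays. The fit with the batch term is the only comparison with Wnt1 within the batch, which held 1 Wnt1 array, so batch and group were not separated.

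**Figure D2:**
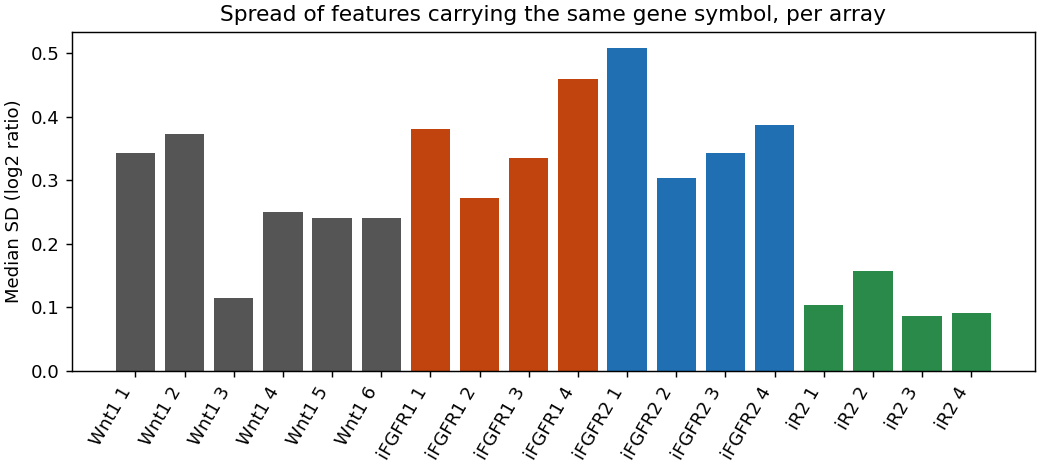
Median SD (log2 ratio) between features carrying the same gene symbol on each array, over the 47 genes with 10 or more features, coloured by group. The 4 iR2 arrays and Wnt1 replicate 3 lie between 0.0857 and 0.158, and the other 13 arrays between 0.241 and 0.507.

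**Figure D3:**
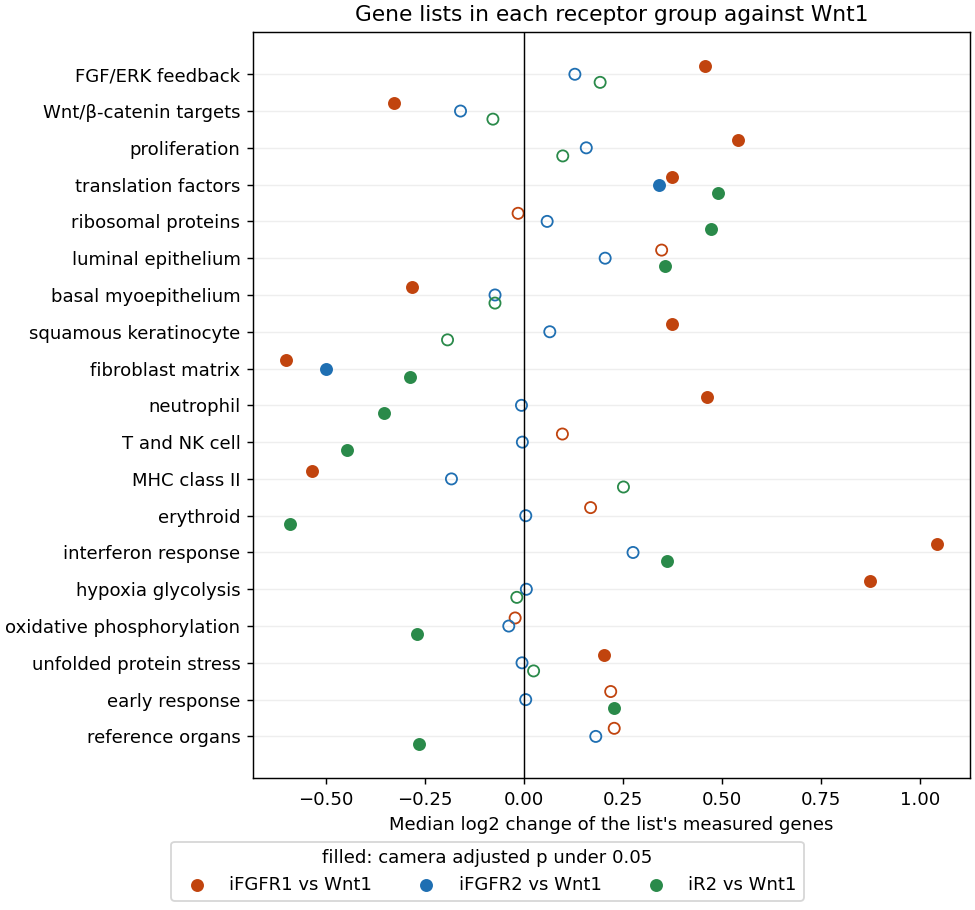
Median log2 change of the measured genes of each list in iFGFR1, iFGFR2 and iR2 against Wnt1, for lists called in at least 1 of the 3 comparisons (filled: camera adjusted p under 0.05; open: not past). Interferon response genes lie at 1.04 in iFGFR1, and ribosomal protein genes at 0.47 in iR2.

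The receptor groups were also compared directly. In iFGFR2 against iFGFR1, Snorc was higher by 4.04 (SE 0.56, 16.4-fold, adjusted p = 0.000691), Aldh1a1 by 3.71 (SE 0.49), Apod by 3.44 (SE 0.72), Fbp1 by 3.36 (SE 0.87) and Tex36 by 2.92 (SE 0.49). The Fbp1 call ended without any 1 of 16 of the 18 arrays (highest adjusted p = 0.126) and the Apod call without any 1 of 3 (0.059), both highest without iFGFR2 replicate 4. Under scaling the Fbp1 call ended (0.155), and with only the compared arrays those of Apod, Krtdap and Fgfr1 did (0.118, 0.0681 and 0.054). Klk7 was lower by a log2 difference of -5.30 (SE 0.86), the related protease gene Klk6 by -3.44 (SE 0.55), the cytokine gene Tslp by -3.31 (SE 0.43), Krtdap by -2.48 (SE 0.48) and Crct1 by -2.29 (SE 0.28). All but Apod (3 of 4) lay past every iFGFR1 array on 4 of 4 arrays. Fgfr1 differed by -1.39 (SE 0.20, adjusted p = 0.00085, 4 of 4). In all 360 genes passed, 204 higher and 156 lower, with 2755 at an unadjusted p under 0.05. The count was 178 after scaling, 202 with array weights and 71 with only the compared arrays.

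By lists, hypoxia and glycolysis genes had a median of -0.92 in iFGFR2 against iFGFR1 (3 of 21 fell, 13 adjusted over the list alone; camera adjusted p = 2.87e-10, adjusted p = 0.211 with an estimated correlation), with Car9 at -1.22 (SE 0.26). Interferon response genes had a median of -0.84 (3 of 22 fell, 8 adjusted over the list alone; camera adjusted p = 4.87e-08, adjusted p = 0.292 with an estimated correlation). Proliferation genes had a median of -0.35 (2 of 43 fell, 3 adjusted over the list alone; camera adjusted p = 1.66e-06, adjusted p = 0.211 with an estimated correlation). Neutrophil genes had a median of -0.50 (4 of 16 fell, 7 adjusted over the list alone; camera adjusted p = 4.68e-05), a call that held with an estimated correlation (adjusted p = 0.0424 with an estimated correlation), with S100a9 at -1.93 (SE 0.30) and S100a8 at -2.23 (SE 0.42). Basal and myoepithelial genes had a median of 0.56 (1 of 23 rose and 1 fell, 4 and 1 adjusted over the list alone; camera adjusted p = 0.0251, adjusted p = 0.211 with an estimated correlation). The fallen member was the keratin gene Krt17 at -2.04 (SE 0.40). Wnt and β-catenin targets had a median of 0.25 (3 of 25 rose and 0 fell, 5 and 2 adjusted over the list alone; camera adjusted p = 0.0281, adjusted p = 0.161 with an estimated correlation), with Wif1 at 2.69 (SE 0.27), Sfrp2 at 2.04 (SE 0.41) and Tnfrsf19 at 1.06 (SE 0.26). Squamous genes had a median of -0.35 (2 of 22 fell, 3 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.254 with an estimated correlation). Early response, adipocyte, FGF and ERK feedback and unfolded protein genes had medians of -0.31, -0.29, -0.21 and -0.19 (camera adjusted p = 0.00959, 0.0281, 0.037 and 0.037; adjusted p = 0.211, 0.359, 0.264 and 0.359 with an estimated correlation). In these 4 lists 0, 1, 1 and 2 genes fell (2, 2, 5 and 3 adjusted over the list alone), and on 4 of 4 iFGFR2 arrays the mean of each of the 11 lists lay past the iFGFR1 mean. They lay past every iFGFR1 array on 1 of 4 for interferon, 2 of 4 for early response, 3 of 4 for hypoxia and 4 of 4 for the other 8. The list count fell to 6 without iFGFR1 replicate 2, iFGFR2 replicate 2 or iFGFR2 replicate 4, and the gene count to 183, 223 and 206 without iFGFR1 replicate 3, iFGFR2 replicate 3 and iFGFR2 replicate 4. The hypoxia, interferon, proliferation, neutrophil and squamous calls held without any 1 array, and the other 6 were each lost without some array (adjusted p up to 0.261). The FGF and ERK feedback call was also lost under quantile normalization (0.0547) and under scaling (0.0513), and fry did not call the squamous, adipocyte, interferon and unfolded protein lists (0.0506 to 0.0783). Without iFGFR1 replicate 2 the basal median was 0.36, and without iFGFR2 replicate 4 the Wnt target and FGF and ERK feedback medians were 0.16 and -0.11. The unfolded protein median was -0.093 or -0.096 without iFGFR1 replicate 4 or iFGFR2 replicate 2.

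In iR2 against iFGFR1, Apod was higher by 4.39 (SE 0.72, 20.9-fold, adjusted p = 0.000719), Snorc by 4.29 (SE 0.56), Fbp1 by 4.26 (SE 0.87), Aldh1a1 by 4.03 (SE 0.49) and Dynap by 3.70 (SE 0.72). Klk7 differed by -5.86 (SE 0.86), Atp1b4 by -3.74 (SE 0.68), the urea cycle gene Cps1 by -3.54 (SE 0.31), S100a8 by -3.44 (SE 0.42) and Krtdap by -2.98 (SE 0.48). All 10 lay past every iFGFR1 array on 4 of 4 arrays. Ribosomal protein genes had a median of 0.57 (22 of 64 rose, 38 adjusted over the list alone; camera adjusted p = 1.52e-13). Neutrophil genes had a median of -0.80 (7 of 16 fell, 8 fell and 1 rose adjusted over the list alone; camera adjusted p = 2.48e-05). Both calls held (adjusted p = 0.0415 and 0.0305 with an estimated correlation). Hypoxia and glycolysis, interferon, squamous and proliferation genes had medians of -0.93, -0.91, -0.75 and -0.42 (11 of 21, 4 of 22, 7 of 22 and 5 of 43 fell; 17, 10, 11 and 8 adjusted over the list alone; camera adjusted p = 1.75e-07, 0.000266, 0.00132 and 0.000792; adjusted p = 0.201, 0.436, 0.201 and 0.252 with an estimated correlation). The glucose transporter gene Slc2a1 fell by 2.15 (SE 0.43), the vasodilator gene Adm fell by 2.31 (SE 0.49) and the ubiquitin-like gene Isg15 fell by 2.09 (SE 0.45).

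MHC class II genes had a median of 0.46 in iR2 against iFGFR1 (2 of 9 rose, 4 adjusted over the list alone; camera adjusted p = 0.00396, adjusted p = 0.068 with an estimated correlation), with Cd74 at 2.35 (SE 0.34). Basal and myoepithelial genes had a median of 0.49 (5 of 23 rose and 1 fell, 7 and 1 adjusted over the list alone; camera adjusted p = 0.00491, adjusted p = 0.0833 with an estimated correlation). Wnt and β-catenin targets had a median of 0.21 (7 of 25 rose and 3 fell, 7 and 4 adjusted over the list alone; camera adjusted p = 0.0207, adjusted p = 0.068 with an estimated correlation), with Lgr5 at 2.80 (SE 0.47). T and NK cell genes had a median of -0.43 (4 of 18 fell, 6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0128, adjusted p = 0.068 with an estimated correlation). Reference organ, adipocyte, erythroid and oxidative phosphorylation genes had medians of -0.38, -0.35, -0.76 and -0.19 (8 of 28, 6 of 18, 2 of 6 and 8 of 80 fell; 9, 6, 4 and 8 adjusted over the list alone; camera adjusted p = 0.000883, 0.0124, 0.0366 and 0.00415; adjusted p = 0.109, 0.252, 0.16 and 0.252 with an estimated correlation). Fibroblast and matrix genes had a median of 0.32 (4 of 27 rose and 2 fell, 5 and 2 adjusted over the list alone; camera adjusted p = 0.0325, adjusted p = 0.493 with an estimated correlation), which turned to -0.22 under scaling and to -0.68 with the batch term. That term rests on Wnt1 replicate 3 alone, whose fibroblast mean was -0.83, against -2.03 to -1.79 on the other Wnt1 arrays. The turn to -0.68 follows from that array, and calls the term ends here cannot be told from traits of that tumour. On 4 of 4 iR2 arrays the mean of each of the 15 lists lay past the iFGFR1 mean. They lay past every iFGFR1 array on 0 of 4 for fibroblast, 1 of 4 for interferon, 3 of 4 for squamous and 4 of 4 for the other 12. The fibroblast call was lost without any 1 of 3 arrays (highest adjusted p = 0.156) and the erythroid call without any 1 of 4 (0.0888). Without iR2 replicate 4 the Wnt target median was 0.12, and without iFGFR1 replicate 3 the interferon median was -0.59. In all 1968 genes passed, 813 higher and 1155 lower (876 and 756 after quantile normalization), with 4406 at an unadjusted p under 0.05, and 781 did with the batch term, 398 higher and 383 lower. Without iR2 replicate 2 or 4 the count was 1172 or 1277, after scaling 3250 (1142 higher, 2108 lower) and with the title number 265 (129 higher, 136 lower). The title number ended the calls of Apod, Fbp1, Dynap, Klk7 and Krtdap (adjusted p = 0.0823 to 0.259). It also ended 5 list calls, those of Wnt targets, basal, adipocyte, T and NK cell and erythroid genes (0.0577 to 0.15). Every iR2 title number lies above every iFGFR1 one, so these losses cannot be told from the group difference. The batch term ended the Atp1b4 call (0.351), and fry did not call the fibroblast and interferon lists (0.236 and 0.0619). With the batch term the hypoxia, basal, T and NK cell, MHC class II, oxidative phosphorylation and erythroid calls were lost (adjusted p = 0.0534 to 0.408). Under quantile normalization the adipocyte, erythroid and reference organ calls were lost (0.388 to 0.573), and under scaling the proliferation call (0.0532).

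In iR2 against iFGFR2, the ectonucleotidase gene Nt5e was higher by 1.76 (SE 0.36, 3.39-fold, adjusted p = 0.0195), Steap4 by 1.66 (SE 0.38), Speer4f1 by 1.65 (SE 0.38), the small heat shock gene Hspb1 by 1.62 (SE 0.28) and the proton pump gene Atp6v1a by 1.56 (SE 0.23). Cps1 differed by -2.63 (SE 0.31), Snap91 by -2.53 (SE 0.48), the cardiac gene Pln by -2.24 (SE 0.38), the corneal gene Kera by -2.18 (SE 0.43) and Spink4 by -2.17 (SE 0.43). All 10 lay past every iFGFR2 array on 4 of 4 arrays. The iFGFR2 means of the 5 lower genes were -5.94, -4.43, -1.52, -3.54 and -1.29, below the reference. The calls of Nt5e, Steap4 and Speer4f1 ended without any 1 of 4, 7 and 7 of the 18 arrays (highest adjusted p = 0.0687, 0.105 and 0.128), and those of Snap91, Kera and Spink4 without iR2 replicate 2 (0.0656, 0.0678 and 0.0672), that of Spink4 also without 1 other array. Under quantile normalization 6 of the 10 calls ended (Steap4, Speer4f1, Snap91, Pln, Kera and Spink4, adjusted p = 0.0619 to 0.109), with the batch term 9 (all but Hspb1) and with the title number 10. Ribosomal protein genes had a median of 0.45 (6 of 64 rose, 29 adjusted over the list alone; camera adjusted p = 7.83e-18, adjusted p = 0.022 with an estimated correlation), with Rpl19 at 1.54 (SE 0.27) and Rps24 at 0.98 (SE 0.19). Reference organ genes had a median of -0.41 (4 of 28 fell, 9 adjusted over the list alone; camera adjusted p = 5.05e-06, adjusted p = 0.0429 with an estimated correlation), with the synaptic gene Snap25 at -1.78 (SE 0.34), the plasma carrier gene Ttr at -1.41 (SE 0.28) and the atrial gene Myl7 at -1.18 (SE 0.22). T and NK cell genes had a median of -0.36 (1 of 18 fell, 8 adjusted over the list alone; camera adjusted p = 0.00273, adjusted p = 0.022 with an estimated correlation), with Cd3d at -1.16 (SE 0.24). Without iFGFR2 replicate 1 this median was -0.20.

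Oxidative phosphorylation, early response, macrophage, erythroid and MHC class II genes had medians of -0.20, 0.37, 0.26, -0.60 and 0.36 in iR2 against iFGFR2 (camera adjusted p = 0.00673, 0.00974, 0.0151, 0.0232 and 0.0424; adjusted p = 0.34, 0.198, 0.425, 0.149 and 0.198 with an estimated correlation). In these 5 lists 3, 0, 0, 1 and 0 genes passed (3, 0, 0, 2 and 1 adjusted over the list alone), and on 4 of 4 iR2 arrays the mean of each of the 8 lists lay past the iFGFR2 mean. They lay past every iFGFR2 array on 1 of 4 for MHC class II and oxidative phosphorylation, 3 of 4 for macrophage and 4 of 4 for the other 5. The macrophage call was lost without iFGFR2 replicate 3 (median 0.17, adjusted p = 0.0884), and the MHC class II, erythroid and early response calls without any 1 of 5, 3 and 2 arrays (highest 0.128, 0.102 and 0.0685). The MHC class II median was 0.16 and 0.23 without iFGFR2 replicate 3 and iR2 replicate 3, and the early response median 0.24 and 0.21 without iFGFR2 replicate 2 and iR2 replicate 1. In all 227 genes passed, 46 higher and 181 lower, with 2600 at an unadjusted p under 0.05. After quantile normalization 19 genes passed, 10 higher and 9 lower, and among genes with a mean ratio above -1 only 7 did. After scaling 1591 passed (342 higher, 1249 lower), with array weights 1138 (409 and 729) and with the title number 2 (1 and 1). Every iR2 title number lies above every iFGFR2 one, so that last count cannot test the group difference. With the batch term 329 passed, 141 higher and 188 lower, 13 of them shared with the 227, and the ribosomal median was 0.12 (adjusted p = 0.056). In that fit 7 of the 8 list calls were lost, all but that of the reference organs, and the macrophage median turned to -0.06. Quantile normalization ended the reference organ, MHC class II and erythroid calls (medians -0.12, 0.36 and -0.21, adjusted p = 0.34, 0.0628 and 0.435), and the title number ended the T and NK cell, erythroid and early response calls (medians -0.12, -0.55 and 0.013, adjusted p = 0.127, 0.0758 and 0.827). Fry did not call the macrophage, MHC class II and early response lists (0.344, 0.0684 and 0.0807). Leaving out iR2 replicate 2 left 19 genes, and leaving out iR2 replicates 4, 1 and 3 or iFGFR2 replicate 3 left 78, 102, 115 and 135.

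The 3 comparisons against Wnt1 shared genes in the same direction. iFGFR1 and iFGFR2 shared 391 genes past the threshold (236 higher, 155 lower, 0 opposite), where lists drawn independently would share 27.9 and 17.4. iFGFR1 and iR2 shared 408 (297 higher, 111 lower, 29 opposite; 55.3 and 38.1 independently), and iFGFR2 and iR2 shared 209 (139 higher, 70 lower, 3 opposite; 13.01 and 7.85 independently). Across genes, which are not independent replicates, the changes correlated at 0.628, 0.390 and 0.572. Unchanged groups simulated with shared Wnt1 arrays, all drawn as noise, gave correlations of 0.399, 0.402 and 0.402. The 0.390 of iFGFR1 and iR2 is not above these, but a correlation of noise alone is no baseline where genes do change. The simulated groups shared at most 0 genes, which was fixed in advance because hardly any gene passes in unchanged groups. That count is no baseline for the shared genes, and the independent counts above leave out the shared Wnt1 arrays. The covariances were 0.164, 0.104 and 0.118, against simulated values of 0.0285, 0.0286 and 0.0286. With the Wnt1 arrays split 3 and 3, the median correlations were 0.466, 0.253 and 0.380, and the median shared genes 59.5, 88 and 26.5, from fewer control arrays in each comparison. The median covariances were 0.134, 0.0751 and 0.0881 there. For iFGFR1 and iR2 the correlation ran from 0.21 to 0.29 over the splits, with no Wnt1 array in common.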

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

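The splits of the samples and the tests of ribosomal protein genes in Wnt1 replicate 3 and of gland tissue were set before their results were seen. The tests of the difference of iR2 from iFGFR2, of milk genes, of a batch shared with iR2 and of an exchange of samples were chosen only after the result was seen.

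Wnt1 replicate 3 stood apart from the other Wnt1 tumours in genes of milk and matrix. Its milk list mean was 3.23, against 0.13 to 0.32 on the other 5 Wnt1 arrays, and its fibroblast and matrix mean was -0.83, against -2.03 to -1.79. Klk7 lay at -0.078 (others -4.99 to -4.67), Klk6 at 3.24 (others -0.72 to 0.17) and Hey1 at 1.77 (others -1.24 to -0.31). Sostdc1 lay at 0.20 (others 2.93 to 3.20) and Fbp1 at -6.41 (others -1.996 to -1.004). It also stood apart in Aldh1a1 (0.45), Camp (-5.02), Car6 (-2.72), Crim1 (-0.18), Dynap (0.39) and Fibin (-2.18). Further genes there were Krtdap (-2.22), Lgr5 (0.069), Mgp (0.68), Pdgfra (-1.92), Phactr1 (-0.20), Rpl19 (0.75), S100a8 (-3.80), Tex36 (1.59) and Tnfrsf19 (0.73). In all, 57 of 608 groups of values held an array whose gap to its nearest neighbour was above Dixon's critical value, 46 for genes and 11 for lists. Chance does this in about 1 of 20 groups. Of the 57, 22 were on Wnt1 replicate 3. The others come to a share of the 608 groups near that of chance, so the arrays listed next need not differ beyond chance.

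Other Wnt1 arrays stood apart in fewer genes. These were Nt5e (0.074), Reg1 (0.43) and Vstm2a (-0.12) on replicate 6, Etv1 (-0.98) and Fgfr1 (-0.056) on replicate 5 and Ube2c (-0.70) on replicate 1. Among iFGFR1 arrays, replicate 4 stood apart in Atp1b4 (-1.66), Atp5k (-0.34), Nt5e (1.52), Reg1 (-1.005) and the adipocyte list (-2.66). Replicate 2 did so in Eif4ebp1 (-0.27) and the reference organ list (-3.07), replicate 1 in Ndufb5 (-0.03) and replicate 3 in the neutrophil list (-0.75). Among iFGFR2 arrays, replicate 1 stood apart in Hp (-5.74), Lgr5 (-2.35), Mgp (0.24), Rtp4 (1.86), S100a8 (-5.82), Wnt and β-catenin targets (0.15) and proliferation (0.058). Replicate 2 did so in Calm4 (-4.91), Cdk1 (0.57), Pabpc1 (0.046), Rps14 (0.17), S100a9 (-6.81) and Snap25 (-2.51). Among iR2 arrays, replicate 1 stood apart in Hspb1 (1.03), S100a8 (-5.94), Wnt and β-catenin targets (0.30), hypoxia and glycolysis (0.30) and early response genes (0.90). Replicate 2 did so in MHC class II (1.21) and replicate 4 in Calm4 (-1.99).

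Lists were called between receptor groups in 34 comparisons by camera's test of the difference itself, with the adjusted p given above. With an estimated correlation 6 of these calls held (1, 2 and 3 in iFGFR2 against iFGFR1, iR2 against iFGFR1 and iR2 against iFGFR2), and with the batch term 7 of the 8 in iR2 against iFGFR2 were lost. In iFGFR2 against iFGFR1 the medians were -0.21 for FGF and ERK feedback, 0.25 for Wnt and β-catenin targets, -0.35 for proliferation, 0.56 for basal and myoepithelial and -0.35 for squamous genes. They were -0.29 for adipocyte, -0.50 for neutrophil, -0.84 for interferon response, -0.92 for hypoxia and glycolysis, -0.19 for unfolded protein and -0.31 for early response genes. In iR2 against iFGFR1 they were 0.21 for Wnt and β-catenin targets, -0.42 for proliferation, 0.57 for ribosomal protein, 0.49 for basal and myoepithelial, -0.75 for squamous and -0.35 for adipocyte genes. They were -0.80 for neutrophil, -0.43 for T and NK cell, 0.46 for MHC class II, -0.76 for erythroid and -0.91 for interferon response genes. Those of hypoxia and glycolysis, oxidative phosphorylation and reference organ genes were -0.93, -0.19 and -0.38. The fibroblast and matrix median was 0.32 and turned to -0.22 under scaling and -0.68 with the batch term, the latter through Wnt1 replicate 3 alone. In iR2 against iFGFR2 they were 0.45 for ribosomal protein, 0.26 for macrophage, -0.36 for T and NK cell, 0.36 for MHC class II and -0.60 for erythroid genes. They were -0.20 for oxidative phosphorylation, 0.37 for early response and -0.41 for reference organ genes.

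The 8 gene counts were set against other splits of the same samples. For every count but that of iFGFR2 against Wnt1, no other split gave as many genes as the real one. The shares were not adjusted over the 8 counts, and with 35 splits no share below 0.0286 was possible. These splits cannot tell a difference between tumours from the array batch of iR2. For iFGFR1, iR2 and the 3 receptor groups against Wnt1 and for the 4 groups, 1 of 100 splits, the real one, gave as many genes (2608, 1199, 2115 and 3311). The highest others gave 395, 438, 1 and 41. For iFGFR2 against iFGFR1, iR2 against iFGFR1 and iR2 against iFGFR2, 1 of 35 splits did (360, 1968 and 227), with the highest others at 56, 0 and 1. For iFGFR2 against Wnt1, 2 of 100 splits gave as many as the real 579. The other, which put Wnt1 replicate 3 with iFGFR2 and iFGFR2 replicate 2 with Wnt1, gave 1747 genes and points to a structure of the samples.

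A first pattern is the higher ribosomal protein median and the lower ratios of the iR2 arrays, which share a low spot spread with Wnt1 replicate 3. The median ribosomal protein gene of Wnt1 replicate 3 lay 0.32 above the other Wnt1 arrays (their own values -0.19 to 0.01), which is consistent with an array batch as part of that difference. For the lower ratios, its deviation correlated across genes with the difference of iR2 from iFGFR2 at 0.0246, below the 0.0846 of another Wnt1 array, but a single linking array excludes nothing. A difference between the tumours was to keep the share of lower calls at 70% or more with the batch term, and the share instead went from 79.7% to 57.1%, under the bound of 60% set against it. Since higher calls went from 46 to 141 and lower calls from 181 to 188, that share decides nothing about the lower ratios, and with 13 calls shared and a term resting on 1 array, batch and tumour cannot be told apart for the lower ratios.

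A second pattern is the rise of Car6, Aqp5 and Scgb2b27 in all receptor groups. Salivary or lacrimal gland tissue in the samples is argued against by a median change of 0.053 over the 24 of 31 gland genes measured, a list written after 5 of its genes had been seen to differ. All 5 of the most abundant salivary genes measured (Amy1, Bpifa2, Prol1, Smr3a and Klk1) changed by under 0.5. No such genes were set for lacrimal gland, for which only the list median speaks. Of the gland genes 4 passed higher, Car6, Aqp5 and Scgb2b27 themselves and Dcpp1 (1.44), and 1 lower, Bhlha15 (-0.79). None of the gland genes is in the milk list. A change in the tumour cells themselves may underlie the rise and stays open as untested.

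A last pattern is the larger number of genes past the threshold without Wnt1 replicate 3 (1414 against 579 in iFGFR2 against Wnt1). Its milk genes, whose median lay 2.10 above the other Wnt1 arrays (their own values -0.54 to -0.42), prompted the explanation of secretory differentiation and so do not test it, and a batch shared with iR2 stays open because removing group means fixed its correlation test near 0 (difference 0.00409). An exchange with iFGFR2 replicate 2 stays open as well: on a scale from the other Wnt1 arrays (0) to the other iFGFR2 arrays (1) over 2332 genes, Wnt1 replicate 3 lay at 0.557 (other Wnt1 arrays -0.12 to 0.14) and iFGFR2 replicate 2 at 0.42 (other iFGFR2 arrays 0.73 to 1.46). Of 448 genes that part the other receptor arrays from the other Wnt1 arrays, 70.3% put Wnt1 replicate 3 nearer to the receptor mean (other Wnt1 arrays 0.893% to 4.46%) and 47.1% put iFGFR2 replicate 2 nearer to the Wnt1 mean (other iFGFR2 arrays 1.34% to 9.60%). Other genes followed the labels, with Scgb2b27, Car6 and Aqp5 at -0.40, -2.72 and 1.43 on Wnt1 replicate 3 and 4.71, 0.80 and 4.54 on iFGFR2 replicate 2, so an exchange and a real difference between tumours cannot be told apart.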

How the results depend on the processing

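The batch term, the fits to 13 and to 16 arrays, the filter on the mean ratio, and scaling for lists and named genes were chosen only after the result was seen. Of 66 list calls and 98 named gene calls, all held when each array was centred on its median, 44 and 81 held without any 1 array, and 6 of the list calls held with an estimated correlation. Quantile normalization kept 52 and 89, scaling to 1 median absolute deviation 60 and 94, and the batch term 47 and 72. The number in the sample title as a covariate kept 45 and 62, and its losses in iR2 cannot be told from the group. Fry kept 51 list calls, the 13 arrays outside the batch 24 of 25, array weights 97 gene calls, the probe of largest variance 98 and the arrays of the compared groups alone 74 of 81. The cause was not tested except where fewer arrays or genes entered or the threshold itself was moved. Signal over background was not analysed here. Filters on missing values moved nothing, since no cell is empty. No paired analysis was possible because replicate numbers are in accession order and pair no samples.

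For iFGFR1 against Wnt1, 1137 genes also passed a 2-fold limit. For iFGFR2 against Wnt1 (579) the count was 143 with only the compared arrays, 307 at 2-fold, 1445 at an adjusted p under 0.10. It was 1099 with iR2 pooled in, 1414 with the batch term (here the same fit as without Wnt1 replicate 3) and 2332 on 16 arrays. For iR2 against Wnt1 (1199) it was 2817 after scaling, 5207 with array weights, 2317 with only the compared arrays, 52 with the title number. It was 485 at 2-fold, 2117 at 0.10, 304 with the batch term and 2147 on 16 arrays. For the 3 receptor groups (2115) it was 3457 with weights, 659 with the title number, 418 at 2-fold, 3186 at 0.10 and 3408 on 16 arrays. For iFGFR2 against iFGFR1 (360) it was 178 after scaling, 202 with weights, 71 with only the compared arrays, 704 at 0.10 and 610 on 16 arrays. For iR2 against iFGFR1 (1968) it was 3250 after scaling, 265 with the title number, 1112 at 2-fold. It was 2957 at 0.10, 781 with the batch term and 1078 among genes with a mean ratio above -1. For iR2 against iFGFR2 (227) it was 19 after quantile normalization, 1591 after scaling, 1138 with weights, 2 with the title number, 562 at 0.10 and 7 with a mean ratio above -1. Over the 4 groups (3311) it was 6066 with weights and 4969 at 0.10.

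With an estimated correlation 0 lists were called in each comparison against Wnt1, 1 in iFGFR2 against iFGFR1, 2 in iR2 against iFGFR1 and 3 in iR2 against iFGFR2. Fry called 0 lists in iFGFR2 against Wnt1 and 7 in iFGFR2 against iFGFR1. Scaling gave 4 lists in iFGFR2 against Wnt1 and 15 in iR2 against iFGFR2, and quantile normalization 6 in iR2 against Wnt1. The batch term gave 1 list in iFGFR2 against Wnt1, 12 in the 3 receptor groups and 5 in iR2 against iFGFR2. The 13 arrays gave 1 in iFGFR2 against Wnt1, and the title number 1 in iFGFR2 and 3 in iR2 against Wnt1. With the Wnt1 arrays split 3 and 3, iFGFR1 and iFGFR2 correlated at 0.466 and shared 59.5 genes, iFGFR1 and iR2 0.253 and 88, and iFGFR2 and iR2 0.380 and 26.5.

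Leaving out each array in turn gave 1750 to 3084 genes for iFGFR1, 99 to 1470 for iFGFR2, 303 to 1883 for iR2 and 1221 to 2831 for the 3 receptor groups against Wnt1. It gave 183 to 530 for iFGFR2 against iFGFR1, 1172 to 2338 for iR2 against iFGFR1, 19 to 326 for iR2 against iFGFR2 and 2276 to 4160 for the 4 groups. The lists called were 12 to 14, 1 to 3, 7 to 12 and 6 to 9 against Wnt1, and 6 to 11, 13 to 17 and 6 to 9 between receptor groups.

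Some directions turned. Reference organ genes in iR2 against Wnt1 went to 0.069 under quantile normalization, early response genes there to -0.19 with the title number and interferon genes to -0.11 with the batch term. Fibroblast genes in iR2 against iFGFR1 went to -0.22 under scaling and -0.68 with the batch term, where macrophage genes in iR2 against iFGFR2 went to -0.056 and Hoxa10 in iR2 against Wnt1 to 0.27. The batch term rests on Wnt1 replicate 3 alone, so turns under it cannot be told from traits of that tumour. The rest were transgene-related genes not past the threshold. Wnt1 in iR2 against iFGFR2 went to 0.038 under quantile normalization, 0.33 under scaling, 0.11 with weights and 0.65 with the title number. Against Wnt1 with the title number it went to 0.18 in iFGFR1, 0.24 in iFGFR2, 0.89 in iR2 (0.092 under scaling) and 0.44 in the 3 receptor groups. With weights it went to -0.14 in iFGFR2 and -0.032 in iR2 against iFGFR1, the latter also -0.030 with the batch term. Fgfr1 in iFGFR2 against Wnt1 went to 5e-04 after centring and 0.20 with the title number, where Fgfr2 in iR2 went to 0.29. Fkbp1a went to 0.12, 0.036 and 0.29 in iFGFR1, iFGFR2 and the 3 receptor groups against Wnt1 with the title number, and to 0.000826 in iFGFR2 against iFGFR1 under scaling.

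Without 1 array, Wnt1 ranged from -0.33 to 0.20 in iFGFR2 and -0.23 to 0.046 in iR2 against Wnt1. It ranged from -0.18 to 0.35 in iFGFR2 and -0.076 to 0.20 in iR2 against iFGFR1, and -0.26 to 0.27 in iR2 against iFGFR2. Fkbp1a ranged from -0.27 to 0.11 in iFGFR1, -0.029 to 0.20 in iR2 and -0.17 to 0.018 in the 3 receptor groups against Wnt1. It ranged from -0.25 to 0.13 in iFGFR2 and -0.024 to 0.36 in iR2 against iFGFR1. Fgfr1 in iFGFR2 against Wnt1 ranged from -0.16 to 0.089, and Fgfr2 in iFGFR2 against iFGFR1 from -0.11 to 0.29.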

Other observations

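Several genes outside the leading groups also differed. Prom1, a membrane protein of progenitor cells, rose by 2.15 (SE 0.19) in the 3 receptor groups against Wnt1 and lay above every Wnt1 array on 12 of 12 arrays, and Arg1 rose by 2.01 (SE 0.28, 11 of 12). Cd3d, part of the T cell receptor complex, rose by 0.82 (SE 0.22, 4 of 4) in iFGFR1 against Wnt1, where the iR2 arrays fell by 0.80. Between iFGFR2 and iFGFR1, Pdgfra was higher by 2.18 (SE 0.31), Fbln1 by 1.14 (SE 0.23) and Fbln2 by 1.12 (SE 0.21), each on 4 of 4 arrays, although the fibroblast and matrix list was not called there.

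Of the 29 lists, 8 were called in no comparison by camera. Fry called 2 of these, mesenchymal transition genes in the 3 receptor groups (adjusted p = 0.0259) and in iR2 against Wnt1 (median -0.20, adjusted p = 0.0475) and B and plasma cell genes in iR2 against iFGFR2 (median -0.25, adjusted p = 0.0417). In the 3 receptor groups against Wnt1 the medians were -0.07 for the transgene-related genes, 0.02 for FGF ligands and receptors, -0.14 for milk, 0.19 for skeletal muscle, -0.13 for endothelium, -0.29 for angiogenic factors, -0.06 for B and plasma cells and -0.19 for mesenchymal transition genes. The camera adjusted p were 0.949, 0.879, 0.366, 0.268, 0.289, 0.27, 0.6247 and 0.0972. Of the mesenchymal transition list 4 of 19 genes fell and 0 rose, over all genes and adjusted over the list alone. Macrophage and adipocyte genes had medians of -0.18 and -0.22 there (camera adjusted p = 0.621 for both).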
